A study of Homo sapiens with 4 samples.

How the data were processed

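Gene expression was measured in PC-3 cells with Affymetrix arrays, on biotin-labelled cRNA, 48 h after infection with lentivirus carrying a silencing RNA against PDEF (2 arrays) or GFP (2 arrays), per the labels' protocols. The deposited table holds 1 intensity per probe set and array on a linear scale, for 22930 probe sets. The background correction, summarisation and normalization behind these intensities are not given in the sources used here. The intensity unit and scale were read from the deposited values, which include values below 0, and the 4 array medians (142.6 to 148.7) are close to each other. No further normalization between arrays was applied in the main setting.

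Of the 22930 probe sets, 524 are controls and were left out of the test, and 22406 were tested. The design fixed before the data were examined used log2(value + 16). Because 2.26% of the tested values lay below 0 and some had no logarithm, values below 0 were set to 0 first, a step added after seeing the data. Fold changes are on this log2(value + 16) scale, which understates the change of low genes. Groups and replicate numbers came from the sample titles. Names came from the platform's probe annotation, through Entrez gene IDs in the RefSeq gene table of GRCh38.p14. Of the tested probe sets, 19415 had 1 gene symbol, 125 had several and were not named, and 2866 were not in the annotation and are unnamed here. The 19415 covered 11940 genes. A gene is represented by its single-symbol probe set with the highest mean log2 value over the 4 arrays. In 13 genes, probe sets were called in opposite directions.

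siPDEF was compared with siGFP with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), over all 4 arrays and with no covariate, with Benjamini-Hochberg adjustment over the 22406 probe sets and a threshold of 0.05. The fit had 2 residual and 10.2 prior degrees of freedom. The median SE of the log2 fold change was 0.103 for probe sets brighter than the median and 0.418 for dimmer ones. An exact permutation test of 2 against 2 arrays cannot give a p under 0.33, so none was used. Array pairs within a group correlated at 0.9934 (siGFP) and 0.991 (siPDEF) over brighter probe sets, and pairs between groups at 0.9516 to 0.9541.

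The gene lists were fixed before the data were examined: epithelial junction and keratin, mesenchymal, extracellular proteolysis and its inhibitors, TGF-beta response, cell migration and integrins, androgen receptor targets and prostate luminal, SPDEF-associated secretory and goblet, ETS transcription factors, mitosis, DNA replication and S phase, integrated and endoplasmic reticulum stress, interferon response, NF-kappaB and cytokines, hypoxia and glycolysis, sterol and fatty acid synthesis, ribosomal proteins, oxidative phosphorylation, neuroendocrine, markers of fibroblasts, blood and endothelium, and reference genes. Each of the 22 lists was tested on 1 probe set per gene with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 22 lists. At the preset correlation 4 lists passed, and with an estimated correlation 0 passed, where 2 had an unadjusted p under 0.05. With an estimated correlation camera has only the 2 residual degrees of freedom, so few lists could pass. Not passing there does not by itself show that correlated genes made a call. List members without a named probe set were not analysed here.

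The rule for named genes, also fixed beforehand, took SPDEF, then the 12 largest rises and 12 largest falls among representative probe sets that passed, had both siPDEF arrays beyond both siGFP arrays and lay at or above the median intensity, then the 4 members of each list with the smallest p. Names outside the rule are given as chosen after their values were seen.

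The code was tested on simulated data made from these arrays, with 200 of 22406 probe sets changed. Of 2-fold changes, 25 of 26 were recovered among brighter probe sets and 1 of 24 among dimmer ones, and of 4-fold changes 27 of 27 and 10 of 23. Of 111 simulated calls 6 were false. In the simulated set test, 0 of 100 unchanged lists had an unadjusted p under 0.05 and 5 of 5 lists shifted by 0.5 were called. The simulated variances came from the fitted intensity trend and the genes were independent. The simulation therefore checks the code, and cannot test that trend or correlation between genes.

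The alternatives tried were quantile normalization, median centring, pseudocounts of 1 and 64, filters at the 40 and 60 percentiles of mean log2 value, a prior variance without the trend or with robust estimation, the replicate number as a block, each array left out, no _x_at probe sets, a 2-fold threshold, 1 probe set per gene, an estimated correlation and gene means. Added after seeing the data were leaving out probe sets with a value below 0, the fit without the trend at the 60 percentile filter, and the mean of the SPDEF probe sets. No batch was named in the labels.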

Results

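The data are 4 Affymetrix expression arrays of PC-3, an established human prostate cancer cell line that grows without androgen. The cells carried a lentivirus that expressed a silencing RNA against PDEF (2 arrays, siPDEF) or against GFP as the control (2 arrays, siGFP), and the labels place the RNA 48 h after infection. They also call the cells stable lines, so whether the changes are an early response or a difference between established lines is not settled. PDEF is the product of SPDEF, an ETS transcription factor of epithelial cells. The comparison of siPDEF with siGFP asks which transcripts change in PC-3 cells when PDEF is silenced. Median probe set intensity was 142.6 and 145.1 in the siGFP arrays and 148.7 and 147 in the siPDEF arrays. With 2 arrays per group, the number of arrays limits the precision. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

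SPDEF, the targeted gene, read lower in siPDEF on all 5 of its probe sets, by 0.23 to 0.63 on the log2 scale, and none of the 5 passed the test (limma, adjusted p from 0.144 to 0.572). The representative probe set, the brightest of them, read 125 and 198 in the siGFP arrays and 117 and 136 in the siPDEF arrays. Its mean was 162 ± 51.9 (SD, n = 2) against 127 ± 13.7 (SD, n = 2), a log2 fold change of -0.29 (SE 0.23, adjusted p = 0.475). Another probe set had the largest difference, from 96.9 and 123 to 64.1 and 66.1 (log2 fold change -0.63, SE 0.27). On the dimmest probe set, the siGFP arrays read 82.6 and 74.9 and the siPDEF arrays 43.7 and 56.5. The remaining ones read 130 and 96.1 against 83.3 and 88.6, and 111 and 142 against 114 and 95.3. On 3 of the 5 probe sets, both siPDEF arrays lay below both siGFP arrays. The mean over the 5 probe sets was 1.32-fold lower in siPDEF, a log2 fold change of -0.40 (95% interval -0.876 to 0.076, adjusted p = 0.248). The IDs of all 5 probe sets end in _x_at, which marks probes that can also bind other transcripts, and their siGFP readings lay between the 35.2 and 55.8 percentiles of each array. Without siGFP replicate 2, the log2 fold change of the representative probe set was 0.016, of opposite sign. A fall of SPDEF was therefore not established by these arrays, and each direction given here is that of the arrays labelled siPDEF.

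**Figure D1:**
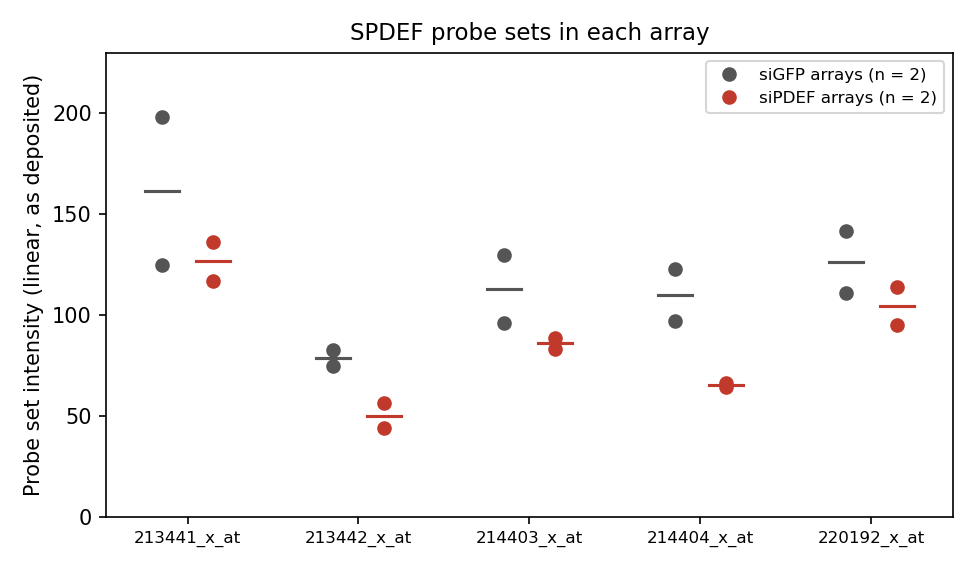
Intensity (linear scale, as deposited) of the 5 SPDEF probe sets in each array, with siGFP arrays in grey and siPDEF arrays in red; each point is 1 array and each line the mean of 2. The siPDEF mean lies below the siGFP mean on each probe set, and the points of both groups overlap on 2 of the 5, the representative one included.

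Beyond the target, EPB41L3, a protein that links the membrane to the cytoskeleton, rose from 59.2 ± 18.6 to 2132 ± 24.9 (SD, n = 2 per group). CSF3, the granulocyte growth factor, rose from 46.2 ± 20.4 to 1102 ± 22.5, and FOXA2, a forkhead transcription factor of endoderm, from 26.8 ± 15.2 to 723 ± 112 (SD, n = 2 per group). Of 2 other FOXA2 probe sets 1 also rose and passed, and the other did not rise and did not pass. In 8 of the 12 named rises (EPB41L3, CSF3, FOXA2, ACKR3, SERPIND1, CDSN, CLEC2B and CNIH3), both siGFP readings lay no higher than the brightest of 9 At control probe sets on the same array. The log2 fold changes of these 8 depend on the pseudocount. Set against that control the 8 rose at least 4.95-fold, and EPB41L3 at least 24.8-fold. The largest falls were those of MATN4, a matrix protein of the matrilin family, from 1105 ± 36.8 to 99.4 ± 11.3, and VGLL1, a cofactor of TEAD transcription factors, from 744 ± 14.6 to 75.6 ± 14.3 (SD, n = 2 per group). KLK6 and KLK5, secreted serine proteases of the kallikrein family, fell by 2.48 and 2.10 on the log2 scale. Of 22406 probe sets, 2136 were higher and 1808 lower in siPDEF at an adjusted p under 0.05 (limma with an intensity trend in the prior variance), and 471 and 231 of these differed at least 2-fold. By the representative probe set of each of 11940 genes, 1375 genes were higher and 1077 lower. The counts rest on how the variance is shared between probe sets. Without the intensity trend, limma called 0 probe sets higher and 0 lower (smallest adjusted p = 0.0609), while 4900 had an unadjusted p under 0.05, and without the trend among the brightest probe sets, at or above the 60 percentile, it called 1638 and 1455 of 8963, a setting added after seeing the data. The counts also rest on each array: they were 325 higher and 147 lower without siGFP replicate 1, 380 and 147 without siGFP replicate 2, 628 and 507 without siPDEF replicate 1, and 494 and 420 without siPDEF replicate 2.

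The other large rises included secreted, matrix and signalling proteins. ACKR3, a scavenging chemokine receptor, rose by 3.51 on the log2 scale (SE 0.14), SERPIND1, the thrombin inhibitor heparin cofactor II, by 3.50 (SE 0.15), and RGS2, which damps G protein signalling, by 3.44 (SE 0.17). LTBP1, which binds latent TGF-beta in the matrix, rose by 3.17 (SE 0.11), and COL6A3, a chain of collagen VI, by 3.06 (SE 0.08). CDSN, an adhesion protein of cornified skin, rose by 3.20 (SE 0.21). The lectins CLEC2B and SIGLEC15 rose by 2.96 (SE 0.25) and 2.93 (SE 0.10), and CNIH3, an auxiliary protein of glutamate receptors, by 2.95 (SE 0.20). As given above, the sizes for ACKR3, SERPIND1, CDSN, CLEC2B and CNIH3 depend on the pseudocount. Among the other falls, the log2 fold change was -2.28 (SE 0.14) for ST6GALNAC5, a sialyltransferase, -2.17 (SE 0.15) for the membrane protein XK, and -2.13 for SPRR2D, a cornified envelope protein read by an _x_at probe set and with close paralogs. RAB25, a small GTPase of epithelial cells, changed by -2.01 (SE 0.14), CLDN1, a tight junction claudin, by -1.73 (SE 0.13), ZNF165 by -1.86 (SE 0.17), C1orf116 by -1.81 (SE 0.20) and BSPRY by -1.75 (SE 0.15). Adjusted p of these 24 genes was 1.13e-05 for ZNF165, 3.66e-05 for C1orf116 and at most 5.53e-06 for those others given with an SE. All 24 passed with quantile normalization and with median centring, and 22 to 24 of them passed when 1 array was left out, while 0 of the 24 passed without the intensity trend.

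**Figure D2:**
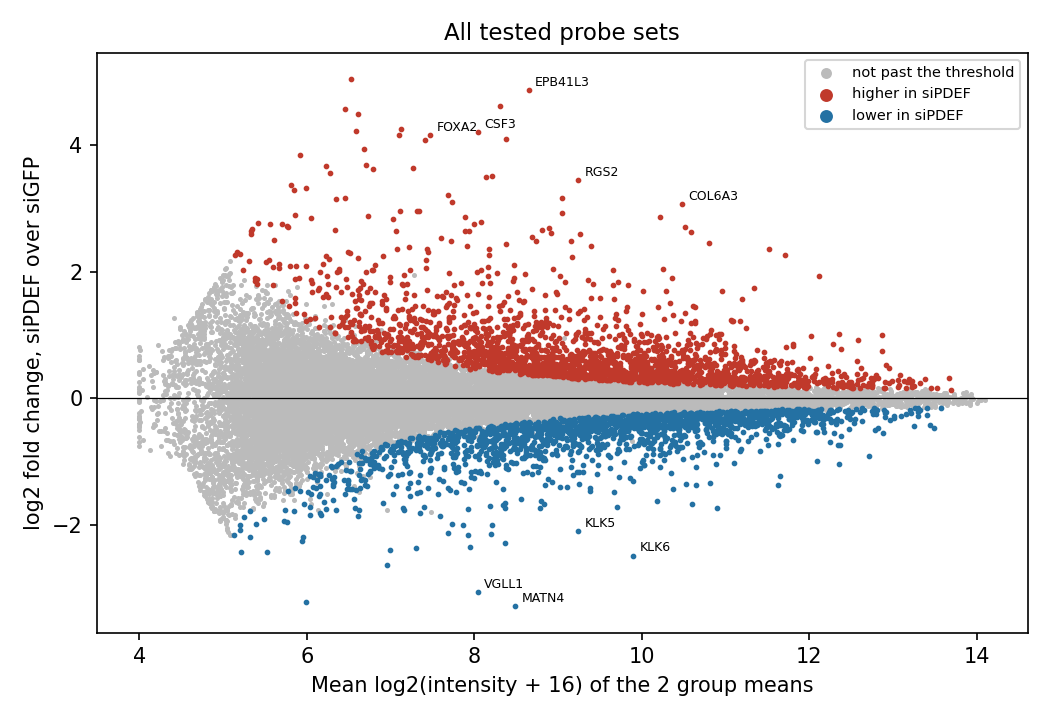
Log2 fold change (siPDEF over siGFP) of each tested probe set against the mean log2(intensity + 16) of the 2 group means, with probe sets past an adjusted p of 0.05 in red (2136 higher) or blue (1808 lower) and the others in grey. Labels mark some of the named genes, from EPB41L3 at 4.86 to MATN4 at -3.28, and dim probe sets at the left need larger differences to pass.

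In the list of epithelial junctions and keratins, 22 of 31 measured members fell, 1 rose and 8 did not pass, and adjusted over the list alone 25 were lower and 2 higher. KRT18, a keratin of simple epithelia, fell from 9216 ± 142 to 4896 ± 92.8 (SD, n = 2 per group, log2 fold change -0.91, adjusted p = 9.38e-08). ESRP1, an epithelial splicing regulator, fell from 2331 ± 56.3 to 905 ± 43.8 (log2 fold change -1.35), beside RAB25 and CLDN1 above. CDH1, which encodes E-cadherin and was chosen after its values were seen, fell from 3093 ± 59.7 to 1524 ± 173 (log2 fold change -1.02). The 1 member that rose was the desmosomal cadherin DSG2, also chosen after its values were seen (log2 fold change 0.30). The list's mean log2 fold change was -0.71, and it was lower than the other genes by camera with a preset correlation (adjusted p = 2.53e-15 over 22 lists), but not with an estimated correlation (adjusted p = 0.319 with an estimated correlation). By fry, which asks whether the genes moved one way on balance, its adjusted p was 0.00848. Without siGFP replicate 1, siGFP replicate 2, siPDEF replicate 1 or siPDEF replicate 2, 11, 10, 16 and 19 members were lower, and 0 were without the intensity trend. Of 10 fibroblast markers 0 were higher and 1, PDGFRA, was lower, to readings within the range of the At controls.

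In the mesenchymal list 13 of 32 measured members rose, 0 fell and 19 did not pass, and adjusted over the list alone 13 were higher and 1 lower. VIM, the intermediate filament of mesenchymal cells, rose from 2273 ± 135 to 8660 ± 342 (SD, n = 2 per group, log2 fold change 1.92, adjusted p = 8.17e-10). COL6A2 rose from 1087 ± 106 to 3552 ± 206 and CDH11, a cadherin of mesenchymal cells read by an _x_at probe set, from 1007 ± 11.5 to 2305 ± 21.9, with COL6A3 given above. Of members chosen after their values were seen, FBN1, a microfibril protein within the range of the At controls in siGFP, rose from 16.8 ± 11.9 to 554 ± 97.3, SNAI2, a repressor of E-cadherin, from 456 ± 0.787 to 1038 ± 0.391, and CDH2, N-cadherin, from 913 ± 21.1 to 1395 ± 56.5. Not all classical members passed: in others chosen after their values were seen, the log2 fold change of ZEB1 was 0.0037, of FN1 -0.09 and of SNAI1 -0.45. The list's mean log2 fold change was 0.60 and its median 0.33. Its adjusted p was 6.55e-06 by camera with the preset correlation, 0.322 with an estimated correlation and 0.00112 by fry. Without siGFP replicate 1 or siGFP replicate 2, 7 members were higher, against 0 without the intensity trend.

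**Figure D3:**
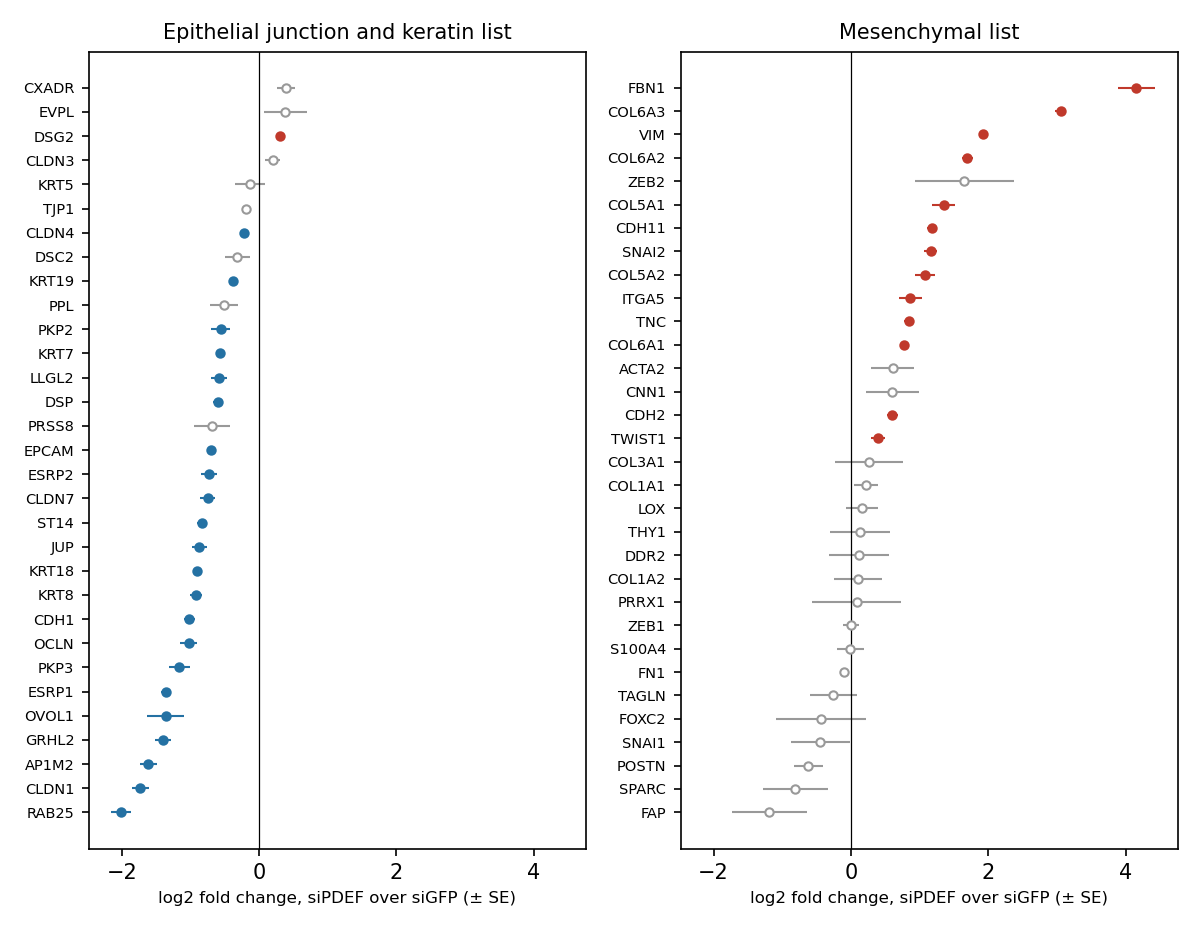
Log2 fold change (siPDEF over siGFP) of each measured gene of the epithelial junction and keratin list (left, 31 genes) and the mesenchymal list (right, 32 genes), with bars for ± 1 SE of the limma fit; filled points passed an adjusted p of 0.05 and open points did not. On the left 22 genes are lower and DSG2 is higher, and on the right 13 genes are higher.

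Proteases of the extracellular space and their inhibitors changed in both directions. Of 25 measured members 4 rose and 2 fell, with 5 and 2 adjusted over the list alone. PLAT, tissue plasminogen activator, rose from 1347 ± 3.01 to 4029 ± 33.2 and the metalloproteinase inhibitor TIMP1 from 2676 ± 35.1 to 4746 ± 63.6 (SD, n = 2 per group). SERPINB5 (maspin) and SERPINE2, both of the serpin family, fell by 0.77 and 0.51 on the log2 scale. The list did not pass by camera (adjusted p = 0.195), and 2 members were higher and 1 or 2 lower when 1 array was left out.

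In the TGF-beta response list, 8 of 24 members rose and 4 fell, with 8 and 5 adjusted over the list alone. TGFBI, a matrix protein, rose from 1277 ± 52.1 to 6612 ± 81.9, ID3, an inhibitor of bHLH transcription factors, from 234 ± 25.6 to 1495 ± 87.6, and COL4A1, a basement membrane collagen, from 225 ± 24.3 to 1331 ± 131 (SD, n = 2 per group), with ID1 at a log2 fold change of 1.74. The list did not pass by camera (adjusted p = 0.083) but did by fry, upward (adjusted p = 0.0135), and 5 to 7 members were higher and 2 or 3 lower with 1 array left out. Among 23 genes of cell migration and integrins 8 rose and 3 fell, with 10 and 3 adjusted over the list alone (camera adjusted p = 0.237). The integrin subunits ITGA3, ITGA6 and ITGA5 rose by 0.93, 0.33 and 0.87 on the log2 scale, and FSCN1, an actin bundler, by 0.76. Most of these calls rest on all 4 arrays: 0 members were higher without siGFP replicate 1, 2 without siGFP replicate 2, 1 without siPDEF replicate 1 and 2 without siPDEF replicate 2, and 0 were lower in each case.

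In the group of androgen receptor targets and prostate luminal genes, 3 of 17 rose and 2 fell, with 3 and 3 adjusted over the list alone (camera adjusted p = 0.917). HOXB13, TMPRSS2 and NDRG1 had log2 fold changes of 0.72, 0.69 and -0.47. HPGD (an _x_at probe set) rose at least 1.97-fold over the At controls of the siGFP arrays, the brightest at 76.5 and 96.2. On siPDEF replicate 2 the brightest At control read 316, so a rise over background is not secured there. All 3 other HPGD probe sets were also higher and 2 of them passed, but they were not set against the At controls. The other TMPRSS2 probe set read -0.33 without passing. In this list 0 members were higher and 0 lower when any 1 array was left out. Among 18 genes tied to secretory and goblet cells, where SPDEF acts, FOXA2 rose on its representative probe set, with its other probe sets given above. SLPI, a secreted protease inhibitor, and FOXA1 fell, with log2 fold changes of -0.57 and -0.73. TFF1, a trefoil peptide, went from 8.80 ± 10.6 to 62.7 ± 23.2 without passing (adjusted p = 0.0705). The same 1 and 2 were counted adjusted over the list alone, and the list's mean of 0.30 and median of -0.03 differed in sign (camera upward, adjusted p = 0.917). Of 23 ETS factors 4 rose and 4 fell, with 4 and 5 adjusted over the list alone. ETV1 and ETV5 rose by 1.72 and 1.15 on the log2 scale, while the epithelial factors EHF and ELF3 fell by 0.91 and 0.53. This list's mean was 0.01 and its median -0.13, with camera downward (adjusted p = 0.764). With 1 array left out, 1 or 2 ETS factors were higher and 0 or 1 lower, and in the secretory list 1 was higher and 0 or 2 lower.

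Of 33 mitosis genes 16 rose by small amounts, 1 fell and 16 did not pass, with the same counts adjusted over the list alone and with DLGAP5, HMMR, TOP2A and NDC80 at log2 fold changes of 0.53, 0.42, 0.45 and 0.45. The mean log2 fold change was 0.17, and camera gave an adjusted p = 0.000665 with the preset correlation and an adjusted p = 0.563 with an estimated correlation, with 0.0209 by fry. These calls depended on each array: 0 members were higher without siGFP replicate 1, 1 without siGFP replicate 2, 3 without siPDEF replicate 1 and 2 without siPDEF replicate 2. Of 30 genes of DNA replication and S phase 9 rose and 0 fell, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.104, fry upward, adjusted p = 0.0229). POLE2, RRM2, MCM6 and TYMS had log2 fold changes of 0.41, 0.31, 0.30 and 0.25, while 2 dimmer TYMS probe sets read -0.50 and -0.36 without passing. Of these 30 genes 2 were higher without siPDEF replicate 1, and 0 without siGFP replicate 1, siGFP replicate 2 or siPDEF replicate 2.

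Hypoxia and glycolysis genes also counted more rises, 7 of 27 against 2 falls, with 9 and 2 adjusted over the list alone. CA12, a carbonic anhydrase, rose by 1.34, ALDOC, an aldolase, by 0.95 and VEGFA, the angiogenic growth factor, by 0.64 on the log2 scale, while the glucose transporter SLC2A1 fell by 0.60. Camera gave an adjusted p = 0.0241, an adjusted p = 0.592 with an estimated correlation and an adjusted p = 0.0596 after median centring, and fry an adjusted p = 0.0728. It was 0.0842 without siGFP replicate 1 and 0.0809 without siPDEF replicate 2, 0.0981 at the 60 percentile filter and 0.0825 without the intensity trend. Leaving out arrays, 1, 1, 2 and 2 members were higher without siGFP replicate 1, siGFP replicate 2, siPDEF replicate 1 and siPDEF replicate 2. Stress genes of the integrated and endoplasmic reticulum responses split, 7 of 26 higher and 9 lower, with 9 and 12 adjusted over the list alone (camera adjusted p = 0.237, fry downward, adjusted p = 0.0461). ATF3, SLC3A2 and TRIB3 fell by 1.05, 0.80 and 0.56 on the log2 scale. VLDLR, within the range of the At controls in siGFP, rose at least 2.85-fold over those of the siGFP arrays. It has the same limit as HPGD from the At control of 316 on siPDEF replicate 2. With 1 array left out, 1 or 2 stress genes were higher and 2 to 5 lower.

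Interferon response genes were 4 higher and 6 lower of 32, with 4 and 7 adjusted over the list alone (camera adjusted p = 0.195). ISG20, an exonuclease, and IFI16, a DNA sensor read by an _x_at probe set, rose by 1.52 and 0.78 on the log2 scale, and IFIH1, an RNA sensor, and MX1, an antiviral GTPase, fell by 0.84 and 0.95. A second, dim IFIH1 probe set read 0.15 without passing. With 1 array left out, 2 interferon members were higher and 0 or 2 lower. In the NF-kappaB and cytokine list 5 of 25 rose and 6 fell, with 6 and 6 adjusted over the list alone. Besides CSF3, IL11 rose from 87.2 ± 9.31 to 690 ± 4.39 and CCL2 from 929 ± 107 to 1906 ± 31.2 (SD, n = 2 per group), while TNFAIP3, a brake on NF-kappaB, fell from 1487 ± 0.528 to 707 ± 21.5. Its mean of 0.16 was opposite in sign to its median of -0.13 and to camera, which was downward (adjusted p = 0.54), and 3 or 4 members were higher and 1 to 3 lower with 1 array left out.

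Of 22 genes of sterol and fatty acid synthesis 1 rose and 4 fell, with 2 and 4 adjusted over the list alone (camera adjusted p = 0.083, fry downward, adjusted p = 0.0209), and DHCR7, SQLE, EBP and CYP51A1, enzymes of cholesterol synthesis, fell by 0.73, 0.66, 0.35 and 0.29 on the log2 scale. With 1 array left out, 0 sterol genes were higher and 1 or 2 lower, and 0 ribosomal protein genes were either. Of 37 ribosomal protein genes 0 rose and 2 fell, RPL13 and RPS20, with 0 and 0 adjusted over the list alone (camera adjusted p = 0.34), both genes read by _x_at probe sets. In oxidative phosphorylation 8 of 38 rose and 2 fell, with 8 and 3 adjusted over the list alone (camera adjusted p = 0.43), among them ATP5F1A, NDUFS4, SDHA and UQCRC1 at 0.43, 0.49, 0.40 and 0.34. Most of these calls were lost with 1 array left out: 0 and 1 members were higher without siGFP replicate 1 and siGFP replicate 2, 3 and 1 without siPDEF replicate 1 and siPDEF replicate 2, and 0 were lower. Of 15 neuroendocrine genes 3 rose (ENO2, SCG5 and CALCA) and 0 fell, as also adjusted over the list alone (mean 0.03, median -0.06, camera upward, adjusted p = 0.54), with fewer higher when 1 array was left out. CALCA, read by an _x_at probe set within the range of the At controls in siGFP, rose at least 1.52-fold over those of the siGFP arrays. It has the same limit as HPGD from the At control of 316 on siPDEF replicate 2. Of its 3 other probe sets 2 were also higher and 0 passed.

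Most markers of other cell types were dim: 8 of 10 fibroblast, 10 of 11 blood and 9 of 9 endothelial markers lay below the median intensity. Of 10 fibroblast markers 0 rose and 1 fell, with 0 and 0 adjusted over the list alone. The list's mean was -0.11 and its median 0.09, with camera downward (adjusted p = 0.917). Of 11 blood and 9 endothelial markers 0 rose and 0 fell on the representative probe set, as also adjusted over the list alone (camera adjusted p = 0.642 and 0.54). Of 2 other probe sets of the endothelial marker PECAM1, 1 passed, in the direction of the representative one. Among 14 genes used as references 3 rose and 1 fell, with 3 and 2 adjusted over the list alone (camera adjusted p = 0.507): SDHA, PSMB2 and GUSB had log2 fold changes of 0.40, 0.33 and 0.34 and YWHAZ of -0.19, directions that held with quantile normalization and median centring, though 0 or 1 were higher and 0 lower with 1 array left out. The 3' minus 5' log2 difference of the GAPDH control, a measure of RNA integrity, averaged -0.185 in siGFP and -0.162 in siPDEF, and that of ACTB 0.0829 and 0.12.

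**Figure D4:**
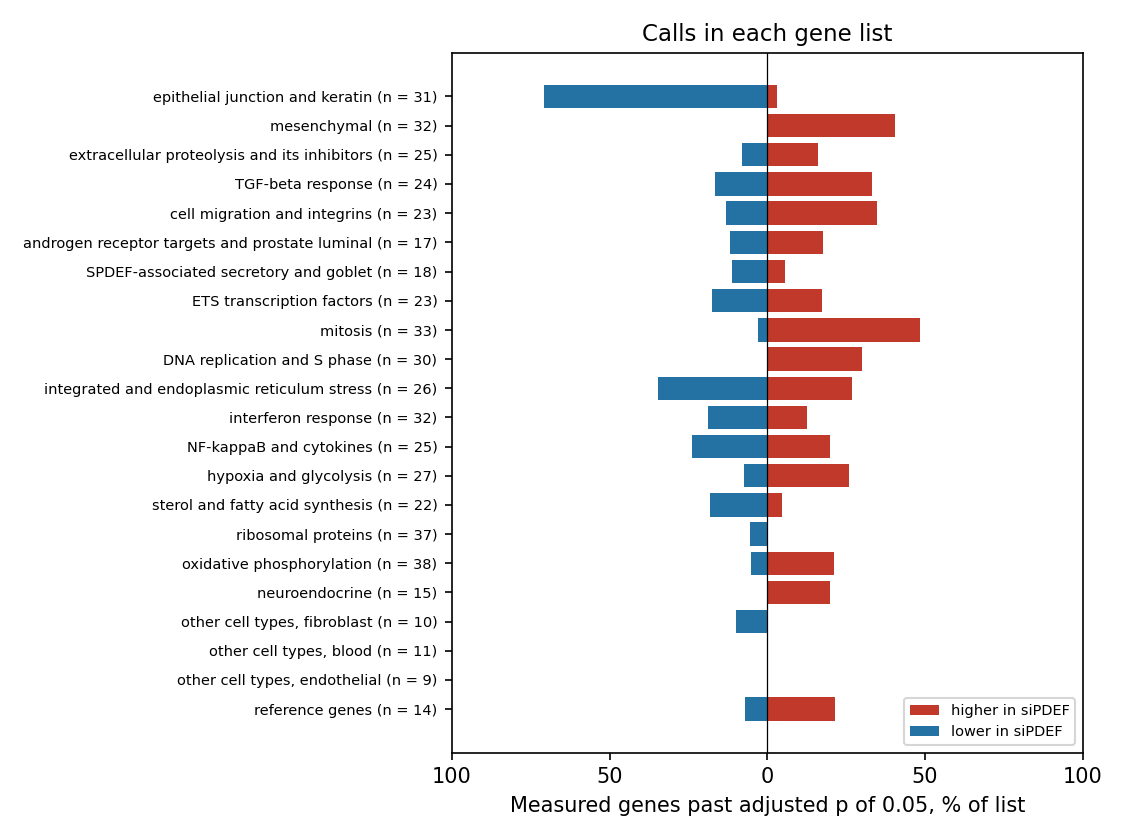
Share of the measured genes of each list, in percent, past an adjusted p of 0.05 and higher (red, to the right) or lower (blue, to the left) in siPDEF, with the number of measured genes in brackets. The epithelial list has 22 of 31 genes lower and the mesenchymal list 13 of 32 higher, and the blood and endothelial lists have 0.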

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

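All tests of explanations in this part were chosen after the results were seen, except that of scaling between arrays. Control probe sets were left out of the main test. When they were tested with the rest, 7 of 524 were higher in siPDEF than in the control arrays and 2 were lower (limma, adjusted p under 0.05). The human control AFFX-HUMRGE/M10098_5_at rose from 1650 to 2495, a log2 fold change of 0.583 (adjusted p = 0.0101). The other probe sets of that control read 974.5 against 1959 (3' end) and 689.3 against 1625 (middle) without passing. The spike-in controls AFFX-BioBcopy42-5_at and AFFX-BioBcopy48-M_at were higher by 0.378 and 0.358 on the log2 scale, AFFX-BioCcopy40-5_at and AFFX-BioCcopy42-3_at by 0.352 and 0.269, and AFFX-BioDncopy34-5_at and AFFX-BioDncopy49-5_at by 0.245 and 0.261. The median difference over 428 spike-in probe sets was 0.071. The 2 lower controls were AFFX-HUMISGF3A/M97935_5_at, from 421.5 to 290.7 (log2 fold change -0.512), and AFFX-ThrX-3_at (-0.657).

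The targeted gene SPDEF did not pass the test while 3944 probe sets did. The test of a signal too dim to show a 2-fold fall left that open. At a pseudocount of 1 the 95% interval of the mean log2 fold change of SPDEF reached -1.07, beyond a 2-fold fall. At 16 and 64 it ended at -0.876 and -0.592, where the added pseudocount makes a halving of these dim readings smaller than 1. Those bounds therefore do not exclude a 2-fold fall either. The criterion of the interval replaced a first one after its result was seen. By the first, at a pseudocount of 16, single SPDEF probe sets needed falls of 0.716 to 1.01 for a call. Of the 5, 1 needed more than 1, which was taken to speak against a dim signal, with the same limit of the scale. Probe sets that also bind other transcripts stay open too, since 5 of the 5 SPDEF probe sets are of the _x_at kind and no other probe set reads the gene. A weak silencing at the RNA level may also account for the pattern, and was not tested apart from these.

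Of the epithelial list 22 of 31 members were lower and 1 higher in siPDEF, and of the mesenchymal list 13 of 32 were higher, though neither list passed with an estimated correlation (adjusted p = 0.319 and 0.322). That test has only 2 residual degrees of freedom. The estimated correlations, 0.011 and -0.0203, were close to or below the preset 0.01, so a higher estimated correlation does not account for the loss. With so few degrees of freedom, these estimates cannot show how correlated the members are. RNA degradation in 1 group is argued against by a largest difference of 0.037 in the 3' minus 5' control values. Fibroblasts among the siPDEF cells are argued against as the whole cause only on the assumption that they lack the epithelial transcripts. Added cells would lower each transcript they lack by 1 factor. Which members fibroblasts express was not checked, and those members would fall less. RAB25, picked as the member that fell most, fell by at least 1.70 on the log2 scale (95% interval), which takes a share of 69.1%. The intervals of 27 of the 31 members lay above that, with CLDN4 at -0.22 and DSG2 at 0.30. A smaller share is not excluded. This test followed 2 others set aside after their results were seen. In the first, 0 of 10 fibroblast markers were called higher, but 8 were below the median intensity. In the second, at a share of 38.7%, the markers' median intensity in the added cells was at most 118 and that of DCN 1950 to 2210, with no fibroblast sample to set it against. A difference between the infected cell populations other than the silencing cannot be told apart from the silencing, since the design has 0 further groups, such as a second silencing RNA. An effect of silencing PDEF is the biological explanation that the design gives, and it may hold, but SPDEF itself did not pass.

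The response over all probe sets was wide. Differences in scale left between the deposited arrays are argued against as the whole cause. After quantile normalization 4026 probe sets were called, of which 3737 were also among the 3944, all of these with the same direction. The array medians were already close (142.6 to 148.7), so this test cannot speak to the normalization before deposit. An interferon response in the siPDEF cells stays open, since 4 members of the list were higher and 6 lower and their mean log2 fold change of -0.182 decides nothing. A first criterion, a mean at or below 0 with no more members higher than lower, argued against it and was replaced after its result was seen. How much of the width comes from the silencing and how much from a difference between populations stays open.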

How the results depend on the processing

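The epithelial and mesenchymal lists kept their direction and passed under each alternative except the estimated correlation, where their means of -0.71 and 0.60 had adjusted p of 0.319 and 0.322 (range over the other settings 2.05e-20 to 8.02e-10, and 1.36e-08 to 0.000474). The proteolysis list did not pass under any (0.106 to 0.563). With 1 array left out, these means ran from -0.73 to -0.68, 0.57 to 0.63 and 0.17 to 0.24. The lone array was then assumed to vary like the other group. SPDEF did not pass under any alternative, and its log2 fold change ran from -0.59 to 0.016, reversed without siGFP replicate 2. It has no value without _x_at probe sets or at the 60 percentile filter. The 2136 higher and 1808 lower probe sets became 0 and 0 without the intensity trend. With 1 array left out they ran from 325 to 628 and 147 to 507, where fewer arrays give fewer calls. At least 2-fold, 471 and 231 remained by construction, and with 1 probe set per gene, fewer tested, 1469 and 1173 were called. The share of calls that were higher was 54.2%, against 49.3% with quantile normalization and 46.6% with median centring.

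With the replicate number as a block, 2590 probe sets were higher and 2316 lower. The deviations of same-numbered arrays correlated at 0.0114 over all probe sets and at 0.0438 over the brighter ones. These values cannot show whether same-numbered arrays share a culture or a day, which the labels do not say. The block is given for completeness. By camera with the preset correlation the TGF-beta list passed with the block (adjusted p = 0.0118), but not without it (adjusted p = 0.083).

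Lists that did not pass reversed in places, and the cause was not tested. The mean of the androgen receptor targets and prostate luminal list was 0.11 at the 40 percentile filter and -0.0861 to 0.0676 with 1 array left out. The fibroblast list's was 0.11 at that filter, 0.028 without _x_at probe sets, 0.088 with gene means and -0.18 to -0.043 with 1 array left out. The secretory list's was -0.15 at the 60 percentile filter, and its mean stayed above 0 where camera turned downward: 0.24 without probe sets holding a value below 0, and 0.22 without siPDEF replicate 2 in a range of 0.22 to 0.39. The neuroendocrine list turned likewise without the trend (0.029). CLDN5 ran from -0.28 without siPDEF replicate 1 to 1.61. Of the values of 106 named genes, 1297 kept direction and side, 236 no longer passed, 1 newly passed and 1 reversed. Signal over background limits the dim probe sets: 446 of the calls were below the median intensity and 3498 above.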

Other observations

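Gene families were looked at after the data were seen, by the letters that open each symbol, in 221 families of at least 8 genes. By camera with the preset correlation 8 families passed, and 0 passed with an estimated correlation (adjusted p = 0.997 for each). The latter test has only 2 residual degrees of freedom, so few families could pass. What follows describes these arrays. Collagen genes were 11 higher and 0 lower of 32 (adjusted p = 0.000991). Beside the collagen VI chains, the basement membrane chains COL4A1 and COL4A2 rose from 225 to 1331 and from 382 to 1616, and COL13A1, a transmembrane collagen, from 906 to 2327. SMAD genes, which carry TGF-beta and BMP signals, were 4 higher of 8 (adjusted p = 0.0327), with SMAD4, SMAD2, SMAD3 and SMAD1 at log2 fold changes of 0.80, 0.61, 0.59 and 0.40. In the aldo-keto reductase family 5 of 8 were higher and 1 lower (adjusted p = 0.0183). AKR1C3, a steroid-metabolising enzyme, rose by 2.48 on the log2 scale, and AKR1C2 and AKR1C1, within the range of the At control probe sets in siGFP, at least 6.69-fold and 5.22-fold over them, but their sequences are near-identical, so the values are uncertain as values of separate genes. Metallothioneins, also near-identical, were 4 higher of 11 (adjusted p = 0.027), and 3 were higher after median centring.

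The other 4 families that passed were lower. Mitochondrial ribosomal proteins of the MRPL series were 9 lower and 0 higher of 31 (adjusted p = 0.00373), led by MRPL15, from 2316 to 1082, while the MRPS series did not pass (3 higher and 0 lower of 21). Genes whose symbols open with EIF, many of them translation initiation factors, were 15 lower and 1 higher of 46 (adjusted p = 0.0269), with a mean log2 fold change of -0.0869. RNA helicases of the DDX series were 13 lower and 2 higher of 31 (adjusted p = 0.0222), among them DDX21, from 5251 to 3621. Keratins were 7 lower and 1 higher of 34 (adjusted p = 0.00845). KRT75 fell from 5058 to 1937 and KRT34 from 1090 to 386, while KRT10 rose from 2863 to 3639. The directions of all 8 families' means held with quantile normalization and median centring.

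Of the probe sets without a name here, 181 were higher and 155 lower. SERPINA1 is 1 of the 13 genes with probe sets called in opposite directions, with log2 fold changes of 1.79, 1.38 and -1.51. The last went from 102.4 to 27.2, within the range of the At controls in siPDEF, so its size depends on the pseudocount.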
